A study of Oryza sativa with 12 samples.

How the data were processed

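Total RNA of wild-type rice (Nipponbare) and of the spx1spx2 double mutant, each grown with and without phosphate, was hybridized to Affymetrix rice arrays, 12 arrays in 4 groups of 3 biological repeats, per the labels. The deposited value table holds 1 intensity per probe set and array on a linear scale, made with MAS5 per the submitters' processing notes; its version and scaling target are not given in the sources used here. The authors' deposited comparison tables hold log2 fold changes per the file headers, for the wild type without against with phosphate and for the double mutant against the wild type at each phosphate level. The same deposited tables hold a p-value; the test behind it, and whether it was adjusted, are not given in the sources used here, and between 41.7% and 64.6% of its values are tied. The expression summary behind the authors' deposited log2 values is not given in the sources used here either.

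Of 57381 probe sets, 123 labelling and hybridization controls and 64 reporter probe sets were left out, which left 57194. A table of probe sets and genes, with gene names updated through the RefSeq gene table, gave 22436 probe sets with 1 gene, 95 with several and 34663 that are unnamed here. The 1-gene probe sets stand for 17905 genes, of which 2448 have a name beyond a LOC number. All 12 value columns were used.

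Signals were transformed as log2(signal + 16). A probe set was tested when its third-highest value over the 12 arrays reached the median of all values (log2 6.221), and 33422 probe sets were. Array medians of 52.2 to 64.3 units lie close to this level, so the sizes of log2 changes among dim probe sets depend on the 16 units added. The 4 groups were fitted together with limma 3.58.1 in R 4.3.3 (lmFit with 1 coefficient per group, eBayes with a mean-variance trend), and 5 contrasts were taken: phosphate withdrawal in each genotype, genotype at each phosphate level, and their interaction. P-values were adjusted with the Benjamini-Hochberg method over all probe sets tested, and a probe set was called at an adjusted p under 0.05. Tables were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9.

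The code was tested on simulated data with the real arrays' means and spread, with 100 probe sets changed 2-fold and 100 changed 4-fold. For the 4 comparisons of 2 groups it recovered 36% to 39% of 2-fold changes and 58% to 73% of 4-fold changes, and for the interaction 22% and 51%, with 5 to 7 false calls per comparison.

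Gene lists were tested with camera at a preset correlation of 0.01, on 1 probe set per gene (the highest mean log2 signal), adjusted over the lists of a comparison. Lists with fewer than 5 tested genes are given as values. The tests, comparisons, alternatives and list topics were chosen before the data were examined. The lists had been planned by loci and product descriptions, which the tables used here do not hold, so their members were rebuilt from gene names after the tables were seen; counts adjusted over a list alone are therefore not given. The lists cover the SPX and PHO1 family, Pi signalling regulators, phosphate transporters, membrane lipid remodelling, phosphate-sparing glycolysis and respiration, photosystems and light harvesting, carbon fixation, starch and sucrose, cytosolic ribosomal proteins, WRKY factors, pathogenesis-related proteins, diterpenoid phytoalexins, glutathione S-transferases, class III peroxidases, heat shock proteins, flavonoid synthesis, nitrogen uptake and assimilation, iron homeostasis, jasmonate, auxin response, LEA and dehydrins, senescence, dividing cells, root, and sheath or stem wall. A planned list of acid phosphatases had no matched gene. By their names, the genes matched to the pathogenesis-related list are chitinase genes and PBZ1.

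The genes named follow a rule: SPX1, SPX2 and the members of the SPX and PHO1 and the Pi signalling lists; the 10 largest rises and 10 largest falls among called probe sets of 1 named gene whose groups' values do not overlap (for the interaction, without that condition); and of each other list up to 4 called members by size, or its member with the highest signal where none was called. The report prints a selection of these. A gene is given by its probe set with the highest mean log2 signal, and called probe sets of opposite sign are stated.

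The response of the wild type and the genotype effect at +P were compared by r and covariance of log2 changes and by counts called in both, beside 100 simulations in which unchanged groups share the wild-type +P arrays. Genes that differ at least 4-fold the same way in both conditions were counted in windows of 50 neighbouring genes, beside 10000 random gene sets. RNA quality was measured as the log2 ratio of 3-prime to 5-prime signal for 8 control probe sets of 5 transcripts (3 for actin, 2 for Gapdh).

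Alternatives were a pseudocount of 1 or 64, quantile normalization, centring of each array on its median, no filter, a stricter filter at the 75th percentile, a replicate block, no mean-variance trend, omission of each array in turn, a 2-fold minimum, fits to 6 arrays, the authors' deposited tables, and for lists an estimated correlation, fry, the mean of all probe sets of a gene and, added later, unique probe sets (without those whose name marks a match to several transcripts). Chosen after the results were seen were the SPX and PHO1 list without SPX1 and SPX2, and separate wild-type +P arrays for the response of the wild type and the genotype effect at +P (1 array for one and 2 for the other, in each of the 6 ways).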

Results

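Transcript levels were measured on rice microarrays in the wild type and in the spx1spx2 double mutant, which is mutated in 2 genes for SPX-domain proteins, sensors of cellular phosphate status that hold back the PHR transcription factors. Seedlings grew hydroponically for 14 days at 200 µM phosphate and then for 7 days at either 200 µM (+P) or 0 µM (-P). The 2 genotypes and 2 phosphate levels made 4 groups with 3 biological repeats each, 12 arrays in all. The tissue is labelled leaf, while the treatment protocol speaks of shoots. The median signal of an array lay between 52.2 and 64.3 units and the upper quartile between 364 and 402 units. Across probe sets, log2 signals of arrays of the same group correlated with r from 0.948 to 0.963, and those of arrays of different groups with r from 0.897 to 0.950. The number of arrays limits the precision of each comparison. All fold changes are differences of log2(signal + 16), and adjusted p-values come from limma with the Benjamini-Hochberg correction over 33422 probe sets. Where a group mean lies near or under the median signal of 58.6 units, the size of a log2 change depends on the 16 units added, and it is to be read as a direction. Of the genes named below this holds in some comparison for MGD2, SPX1, SPX2, SPX3, SPX5, LIS, HS1, LEA19, Nramp1, ABCG48, KSL7, RAB21, LAC24, CPS4, CYP76M6, CYP76M7, OsC3H40, AO-1, MTP4, ACC2 (LOC4336750), Cht4, STLP3, CDKB2-1 and LOC4341377.

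SPX1 gave 1254, 2306 and 2040 units in the 3 wild-type +P arrays and 16227, 14145 and 14320 units in the wild-type -P arrays. In the double mutant it gave 55.4, 74.1 and 54.6 units at +P and 83.3, 3.98 and 9.42 units at -P. SPX2 gave 1169, 1679 and 1878 units in the wild type at +P and 19207, 17059 and 16053 units at -P. In the double mutant SPX2 stayed at 32.1, 29.0 and 62.5 units at +P and at 2.78, 3.35 and 48.8 units at -P.

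The first comparison asked how the wild type responds to 7 days without phosphate. The SPX and PHO1 family shifted upward, as given below, and single genes of other phosphate lists rose. MGD2, a galactolipid synthase of the pathway that replaces phospholipids in membranes, rose from 55.0 ± 8.92 units, near background, to 6128 ± 627 units (mean ± SD; log2 6.44, SE 0.36, n = 3 per group, adjusted p = 7.36e-08 with limma; 6.78 with a pseudocount of 1 and 5.70 with one of 64). SPX5 rose by 4.44 (SE 0.28), SPX2 by 3.48 (SE 0.38), SPX1 by 3.03 (SE 0.43) and SPX3 by 2.61 (SE 0.55). The name of the SPX5 probe set marks a match to several transcripts, so signal from related genes was not excluded. SPP1, a sucrose-phosphate phosphatase, rose from 1903 to 15738 units. LIS, a terpene synthase gene, rose by 4.89 (SE 1.03), the auxin-conjugating enzyme gene GH3.2 by 2.94 (SE 0.53), the vacuolar iron transporter gene VIT1.2 by 2.74 (SE 0.29) and HS1 by 2.61 (SE 0.43). Falls were ranked only among genes with a name beyond a LOC number and no overlap of the groups. The largest were in the metal transporter gene Nramp1, from 774 to 16.1 units (log2 -4.59, SE 0.38), and in the glutaredoxin genes GRXC10 (log2 -2.83, SE 0.28) and GRXC1 (log2 -2.54, SE 0.23). CEBIP, a chitin receptor gene, changed by log2 -2.36 (SE 0.43), CYP88A5 by -1.96, BGLU18 by -1.80 and the heat shock factor gene HSFA2D by -1.76. In each of these genes other than SPX3, for which it was not required, the 3 arrays of one group lay above the 3 of the other, and the same holds for the largest rises and falls of the next 3 comparisons.

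**Figure D1:**
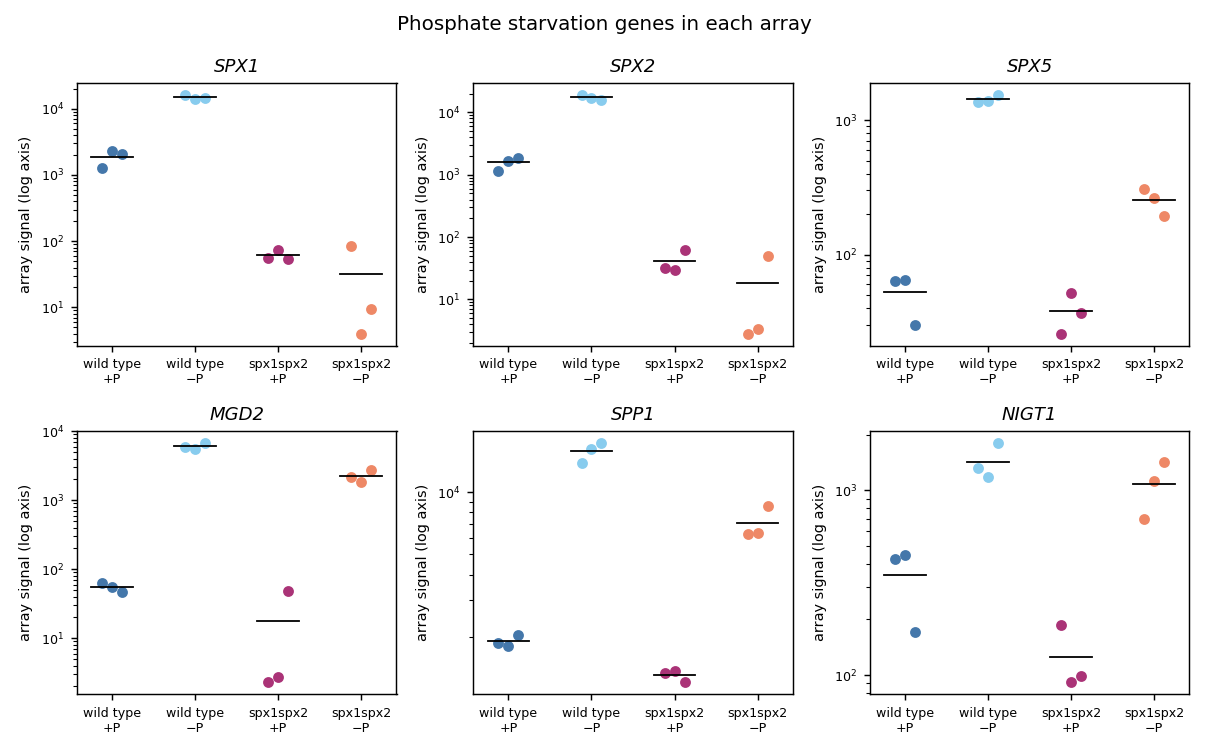
Signal (units, log axis) of 6 genes in each of the 4 groups; points are single arrays and lines are group means, n = 3. MGD2, SPX5, SPP1 and NIGT1 are higher at -P than at +P in both genotypes, and SPX1 and SPX2 stay at 83.3 units or lower in all double mutant arrays.

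Of the 7 tested members of the SPX and PHO1 family, 6 rose and none fell (median log2 2.61, adjusted p = 5.32e-06; adjusted p = 0.026 with an estimated correlation). OsPHO1;2, a gene for a phosphate exporter, rose by 1.17 (SE 0.20), and SPX4 gave 0.35 (SE 0.15, adjusted p = 0.154). OsPHO1;3 rose by 0.54 (SE 0.13), a call lost without wild-type +P array 3 (0.42), wild-type -P array 2 (0.49) or wild-type -P array 3 (0.52). Of 4 Pi signalling regulators, 2 rose: NIGT1, a repressor of nitrate responses, by 2.08 (SE 0.35) and PHR3 by 0.93 (SE 0.22). The call of PHR3 was lost without wild-type +P array 1 (log2 0.83) or wild-type -P array 3 (log2 0.76). PHR1 (log2 -0.07) and PHR2 (log2 -0.15) were not called. Among 7 phosphate transporters 2 rose and 1 fell, with OsPht1;4 up by 1.63 (SE 0.18) and a list adjusted p of 0.449. OsPht1;1 gave log2 -0.86 on its brightest probe set and 1.43 on another, both called, so its direction was not settled. In membrane lipid remodelling MGD2 and MGD3 (log2 1.33) rose and 3 of 5 genes were not called (list adjusted p = 0.112).

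Ribosomal protein genes shifted upward, with 8 of 23 rising and 1 falling (median log2 0.26, adjusted p = 0.0187; adjusted p = 0.489 with an estimated correlation). RPS26 rose by 0.68 and RPS7 by 0.58. This shift lost its call under median centring (median 0.12), without wild-type +P array 1 (0.20) and without wild-type -P array 2 (0.21). The other 18 tested lists had adjusted p from 0.112 to 0.806. Starch and sucrose genes gave 7 rises and 3 falls of 28, with SPP1 up by 3.03 and the starch synthase gene SS1 up by 1.84. Nitrogen genes gave no rise and 4 falls of 18, among them the nitrate reductase gene NIA1 (log2 -0.86) and the ammonium transporter gene AMT1 (log2 -0.76). Iron homeostasis genes gave 3 rises and 6 falls of 22, with NAS3, a nicotianamine synthase gene, up by 1.44. Jasmonate genes gave 7 rises and 1 fall of 30, with JAZ8 up by 2.44. Auxin response genes gave the same counts, with IAA1 (LOC4334069) up by 0.75. Of 6 WRKY factors 3 fell, WRKY24 by log2 -1.32. Photosystem genes gave 1 fall of 7 (PSB28, log2 -0.64) and carbon fixation genes 1 fall of 5 (CFBP1, log2 -0.52). One of 10 pathogenesis-related genes rose and 2 fell, 1 of 14 diterpenoid genes rose, 3 of 6 glutathione S-transferases rose (GSTF1 by 2.17), 1 of 22 heat shock proteins rose (HSP16.9A by 2.03) and 1 of 7 LEA genes rose (LEA19 by 1.95). The lists too small to test gave 1 rise of 2 for flavonoid synthesis, and no call of 3 for class III peroxidases and of 3 for phosphate-sparing glycolysis and respiration.

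Markers of other cells and of senescence were set beside these groups. Of 3 root markers 2 fell, IRT1 (log2 -0.99) and Lsi1 (log2 -0.42), while OsCASP1 gave -0.19. The IRT1 call was lost without wild-type +P array 1 (-0.87) or 2 (-0.92) or wild-type -P array 1 or 2 (-0.95 each), and the Lsi1 call without any 1 of the 12 arrays but wild-type +P array 3 (-0.27 to -0.48). Of 5 senescence genes 2 rose, SGR, which acts in chlorophyll breakdown, by 0.57 and RCCR1 by 0.58 (list adjusted p = 0.375). The SGR call was lost without wild-type +P array 1 (0.55) or 3 (0.54) or wild-type -P array 1 (0.46) or 2 (0.52), and the RCCR1 call without wild-type +P array 1 (0.43) or wild-type -P array 1 (0.45). Dividing-cell genes gave 4 rises of 47 (adjusted p = 0.392) and sheath or stem wall genes 1 rise of 33 (adjusted p = 0.396). Of 8 ratios of 3-prime to 5-prime control signal, from 5 transcripts, 3 were lower by more than 1 SD at -P than at +P: one of 3 actin ratios (log2 difference -0.66), Cyph (-0.50) and one of 2 Gapdh ratios (-0.24).

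In total 4176 of 33422 probe sets changed, 2212 upward and 1964 downward, and 1172 of them by at least 2-fold, 759 upward and 413 downward. Centring each array on its median moved the median change of all probe sets from 0.04 to -0.10 and the split to 1355 upward and 3437 downward, so that directions of small changes are relative to the array scaling. The count fell to 2607 without wild-type +P array 1, to 2481 without wild-type -P array 2, to 2549 without wild-type -P array 3, and to 2458 without the mean-variance trend.

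The second comparison asked what the loss of SPX1 and SPX2 changes while phosphate is supplied. Pathogenesis-related, diterpenoid and jasmonate genes rose as lists. Apart from PBZ1, the pathogenesis-related list holds only chitinase genes by name, so it does not stand for other pathogenesis-related families. Of 10 pathogenesis-related genes 9 rose and none fell (median log2 1.94, adjusted p = 6.44e-07; adjusted p = 0.0265 with an estimated correlation). The chitinase gene Cht2 rose from 230 to 7284 units (log2 4.77, SE 0.33, n = 3 per group, adjusted p = 2.1e-07 with limma), CH16 from 538 to 10447 units (log2 4.23, SE 0.20) and PBZ1, a PR10-type gene, from 6342 to 49575 units (log2 2.98, SE 0.20). Of 14 genes of diterpenoid phytoalexin synthesis 10 rose and 1 fell (median log2 2.15, adjusted p = 0.000128; adjusted p = 0.236 with an estimated correlation). CYP71Z7 rose from 129 to 9951 units (log2 6.10), KSL7 by 4.54, CPS4, a copalyl diphosphate synthase gene, by 3.99 and CYP76M6 by 3.88. CYP76M7 was the member that fell, from 1031 to 7.26 units (log2 -5.48, SE 0.32). The gene matched to this name is LOC4341447 on chromosome 6, 12 genes from SPX1, while CYP76M6 and CYP71Z7 lie on chromosome 2. The name was taken from the gene table, and whether this gene acts in diterpenoid synthesis was not tested. Jasmonate genes gave 15 rises and 1 fall of 30 (median log2 0.66, adjusted p = 0.00014; adjusted p = 0.249 with an estimated correlation), with the repressor gene JAZ11 up by 3.44 and the lipoxygenase gene LOX9 by 3.21. Of 8 ratios of 3-prime to 5-prime control signal, one of 2 for Gapdh and that of ubiquitin were lower by more than 1 SD in these double mutant arrays than in the wild type at +P (log2 differences -0.54 and -0.31).

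**Figure D2:**
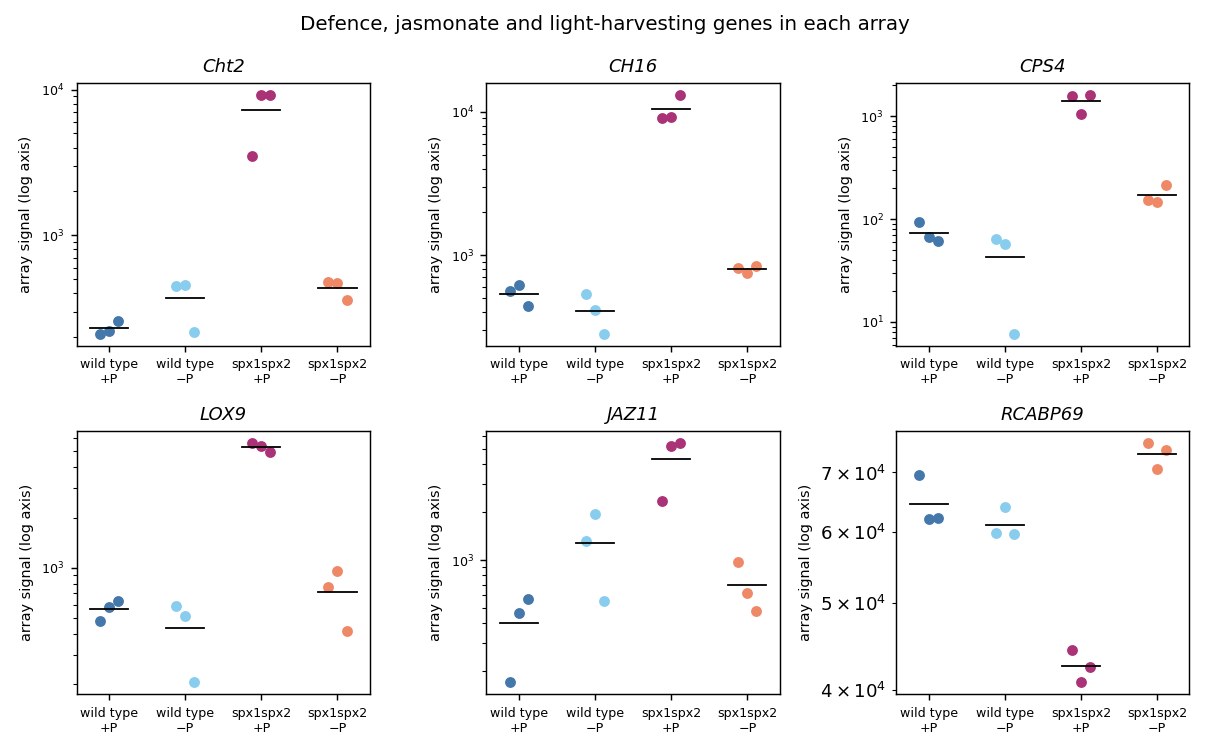
Signal (units, log axis) of 6 genes in each of the 4 groups; points are single arrays and lines are group means, n = 3. Cht2, CH16, CPS4, LOX9 and JAZ11 are highest in the double mutant at +P, where RCABP69 is lowest at a mean of 42508 units.

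Photosystem genes fell, all 7 of 7 (median log2 -0.60, adjusted p = 3.64e-05; adjusted p = 0.236 with an estimated correlation), with PSB28 at -0.70, PSAG at -0.68 and the light-harvesting gene RCABP69 at -0.60. Carbon fixation genes gave 3 falls of 5 (median log2 -0.67, adjusted p = 0.0127; adjusted p = 0.277 with an estimated correlation), with FBPase at -0.69, and this shift lost its call under quantile normalization (median -0.36). RCAA1, the rubisco activase gene, was called at -0.36 and turned to 0.01 under quantile normalization; the call was also lost without wild-type +P array 2 (-0.30) or double mutant +P array 1 (-0.31). The senescence gene SGR rose beside them by 1.72 (SE 0.16) and RCCR1 by 0.49, a call lost without wild-type +P array 1 (0.34) or double mutant +P array 3 (0.47), with a senescence list adjusted p of 0.302. Cytosolic ribosomal protein genes rose, 19 of 23, and 1 fell (median log2 0.86, adjusted p = 2.33e-10; adjusted p = 0.236 with an estimated correlation). RPL7A-2 rose by 1.25, RPS4 by 1.24 and RPS26 by 1.22.

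Late embryogenesis genes gave 3 rises of 7 (median log2 1.11, adjusted p = 0.04; adjusted p = 0.327 with an estimated correlation), with LEA19 up by 6.27 (SE 0.33) and the dehydrin gene RAB21 by 4.21. WRKY factors gave 2 rises of 6, WRKY24 by 1.89 and WRKY71 by 1.34 (median 0.84, adjusted p = 0.04; adjusted p = 0.291 with an estimated correlation). Both lists lost their call without wild-type +P array 1 (medians 0.36 and 0.52) and without double mutant +P array 2 (medians 1.12 and 0.72); the LEA list also lost it with a pseudocount of 1 (1.53) or with unique probe sets (0.72), and the WRKY list under quantile normalization (0.78) or the stricter filter (0.84). Other large rises were those of the transporter gene ABCG48 (log2 5.77), the isocitrate lyase gene ICL (log2 4.48), the laccase gene LAC24 (log2 3.99) and the alternative oxidase gene AOX1 (log2 1.79). AOX1 is 1 of 3 phosphate-sparing genes, of which 1 rose and 1 fell; none of 3 class III peroxidases and none of 2 flavonoid genes was called.

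No tested phosphate list shifted. The mutated genes SPX1 (log2 -4.57) and SPX2 (log2 -4.82) fell to near background, while SPX3 (-0.49), SPX4 (-0.37) and SPX5 (-0.33) were not called, and the SPX and PHO1 list had 1 rise and 2 falls of 7 (adjusted p = 0.102). OsPHO1;3 rose by 0.42, a call lost without wild-type +P array 3 (0.31), double mutant +P array 2 (0.35) or array 3 (0.39), and OsPHO1;2 gave -0.11. Of 4 Pi signalling regulators 1 rose, PHR3 by 2.26 (SE 0.22), and 2 fell, NIGT1 and PHR2 (-0.28); PHR1 gave 0.12. The PHR2 call was lost without wild-type +P array 1 (-0.26) or 3 (-0.25) or double mutant +P array 2 (-0.28) or 3 (-0.27). OsPht1;4 fell, at -1.06 (SE 0.18), and OsPht1;8 rose by 1.36 (SE 0.25), within a transporter list with 1 rise and 1 fall of 7 (adjusted p = 0.875). Membrane lipid genes gave 1 rise and 2 falls of 5 (adjusted p = 0.616), the falls being MGD2 and PLD2 (-1.20), which lies 3 genes from SPX1. MGD2 gave -1.33 (SE 0.36, adjusted p = 0.0147), a call between signals near background (64.2, 54.5 and 46.4 units in the wild type and 2.33, 2.77 and 49.1 in the double mutant) that was lost without double mutant +P array 1 (-1.02) or array 2 (-1.03), and NIGT1 gave -1.32 (SE 0.35, adjusted p = 0.0124), a call lost without wild-type +P array 1 (-1.12) or array 2 (-1.09) and double mutant +P array 2 (-1.15) or array 3 (-1.19). Other falls were ranked only among genes with a name beyond a LOC number and no overlap of the groups. They were largest in OsC3H40 (log2 -6.10), BURP2 (log2 -2.80), AO-1 (log2 -2.46), GER8 (log2 -2.01), the metal tolerance gene MTP4 (log2 -1.87) and OsC3H2 (log2 -1.65). Auxin response genes gave no rise and 10 falls of 30 (adjusted p = 0.0683), starch and sucrose genes 6 rises and 10 falls of 28 (adjusted p = 0.581), with the starch synthase gene GBSS1 at -1.45, and glutathione S-transferases 4 rises of 6 (adjusted p = 0.0626). Nitrogen genes gave 4 rises and 6 falls of 18, with AMT3-2 up by 2.58; their median was 0.13 while the list test pointed downward (adjusted p = 0.943). Iron genes gave 5 rises and 6 falls of 22 (adjusted p = 0.758), with YSL13 up by 2.15, and heat shock proteins 4 rises and 1 fall of 22 (adjusted p = 0.323), with HSP26.2 up by 1.76. The root marker Lsi1 fell, at -0.89 (SE 0.13), and IRT1 at -0.76, a call lost without any 1 of the 12 arrays but wild-type +P array 3 and double mutant -P arrays 1 and 3 (-0.64 to -0.78), while OsCASP1 gave 1.01 (adjusted p = 0.377); dividing-cell genes gave 3 rises and 6 falls of 47 (adjusted p = 0.349) and sheath or stem wall genes 2 rises and 2 falls of 33 (adjusted p = 0.349).

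In total 7899 probe sets differed between the genotypes at +P, 3775 higher and 4124 lower in the double mutant, and 2764 by at least 2-fold, 1812 higher and 952 lower.

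The third comparison asked the same without phosphate. Some starvation genes were lower in the double mutant. The SPX and PHO1 family gave no rise and 3 falls of 7 (median log2 -1.88, adjusted p = 2.35e-08; adjusted p = 0.00896 with an estimated correlation). SPX2 (log2 -9.25) and SPX1 (log2 -8.65) are the mutated genes; in the double mutant they lie near background, and the values run from -10.86 to -7.77 and from -9.83 to -7.37 with pseudocounts of 1 to 64. With both left out, a test added after the results were seen, the list gave 1 fall of 5 (median log2 -0.33, adjusted p = 0.00724; adjusted p = 0.225 with an estimated correlation). SPX5, the gene that fell, was 254 units against 1431 in the wild type (log2 -2.44, SE 0.28, n = 3 per group, adjusted p = 9.16e-05 with limma). Its probe set may also take up signal of related transcripts, such as those of the mutated genes, and this was not tested. SPX3 gave -1.88 (SE 0.55, adjusted p = 0.0993), SPX4 -0.17, OsPHO1;2 -0.33 and OsPHO1;3 0.04. SPP1 was lower by log2 -1.16 (SE 0.12) and NAS3 by -2.01 (SE 0.21). At +P the SPP1 signals were lower too, at 1343, 1370 and 1212 units against 1868, 1810 and 2032 in the wild type. Of other genes named by the rule, not as starvation genes, BURP17 was lower by -1.75 (SE 0.13) and GBSS1 by -1.39 (SE 0.24). GBSS1 was lower at +P too, as given above. Membrane lipid genes gave 3 falls of 5 (median log2 -0.80, adjusted p = 0.0374; adjusted p = 0.219 with an estimated correlation), a shift lost without wild-type -P array 1 (median -0.79) or double mutant -P array 3 (-0.89), with a pseudocount of 1 (-0.81) and with the stricter filter (-0.80). They were PLD2 at -1.13, which was lower at +P too, lies 3 genes from SPX1 and was not called in the starved wild type (0.17), MGD3 at -0.80, a call lost without wild-type -P array 1 (-0.79), wild-type -P array 3 (-0.76) or double mutant -P array 1 (-0.65), and MGD2 at -1.45 (adjusted p = 0.0493), a call lost without any 1 of the 6 wild-type arrays or the 3 double mutant -P arrays (-1.32 to -1.59). None of 4 Pi signalling regulators was called (NIGT1 -0.43, PHR3 0.55, PHR1 0.06, PHR2 -0.01), nor any of 7 phosphate transporters (list adjusted p = 0.186).

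Some defence genes were higher in the double mutant at -P too. Diterpenoid genes gave 3 rises and 1 fall of 14 (median log2 1.01, adjusted p = 0.000294; adjusted p = 0.219 with an estimated correlation), with CYP71Z7 up by 4.32 (SE 0.33) and CYP76M6 by 3.46 (SE 0.42); the shift lost its call with the stricter filter (median 0.72), and CYP76M7 was again the member that fell (log2 -6.44). Pathogenesis-related genes gave 3 rises of 10 (median log2 0.26, adjusted p = 0.0082; adjusted p = 0.219 with an estimated correlation), with PBZ1 up by 1.84 (SE 0.20) and Cht11 by 0.67. Jasmonate genes gave no rise and 1 fall of 30 (median log2 -0.07, adjusted p = 0.321). WRKY76 fell, at -1.53 (SE 0.37), a call lost without wild-type -P array 1 (-1.45) or 2 (-1.25), double mutant +P array 3 (-1.53) or double mutant -P array 1 (-1.46) or 2 (-1.38). Of the 8 ratios of 3-prime to 5-prime control signal, that of ubiquitin was higher by just over 1 SD in the double mutant (log2 difference 0.10). LEA19 rose by 2.43 (SE 0.33), ABCG48 by 3.57 (SE 0.41) and the tubulin gene TUB6 by 1.34 (SE 0.17). OsC3H40 fell (log2 -6.23).

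Other lists shifted by small amounts. Ribosomal protein genes gave a median of 0.22 with no member called of 23 (adjusted p = 1.1e-05; adjusted p = 0.256 with an estimated correlation). Photosystem genes gave a median of 0.18 with no member called (adjusted p = 0.00497; adjusted p = 0.32 with an estimated correlation), lost under quantile normalization (0.04) or without double mutant -P array 1 (0.12). LEA genes gave 1 rise of 7 (median 0.41, adjusted p = 0.0443; adjusted p = 0.432 with an estimated correlation), heat shock proteins 1 fall of 22 (median -0.29, adjusted p = 0.0374; adjusted p = 0.547 with an estimated correlation), and sheath or stem wall genes 1 rise and 1 fall of 33 (median -0.49, adjusted p = 0.0265; adjusted p = 0.432 with an estimated correlation). The LEA shift was lost under median centring (0.45), with a pseudocount of 1 (0.43), with unique probe sets (0.25), without wild-type -P array 1 (0.47) or 3 (0.58), without double mutant -P array 1 (0.33) or 3 (0.40) and without double mutant +P array 1 or 2 (0.41). The heat shock shift was lost with the stricter filter (-0.23) and without wild-type -P array 1 (-0.22) or 2 (-0.25) or double mutant -P array 3 (-0.21), and the wall shift with no filter (-0.16), with the stricter filter (-0.32) and without wild-type -P array 2 (-0.35) or double mutant -P array 2 (-0.22) or 3 (-0.49). The other 11 tested lists had adjusted p from 0.108 to 0.958; among them WRKY factors, with 1 fall of 6, had a median of 0.01 and a test pointing downward.

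In total 849 probe sets differed, 338 higher and 511 lower in the double mutant, and 475 by at least 2-fold, 180 higher and 295 lower. Without wild-type -P array 2 the count was 493, without double mutant -P array 2 it was 451, and without the mean-variance trend it was 545.

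The fourth comparison asked how the double mutant responds to phosphate withdrawal. Several starvation genes outside SPX1 and SPX2 rose here too: MGD2 from 18.1 units, near background, to 2250 units (log2 6.31, SE 0.36, n = 3 per group, adjusted p = 7.09e-08 with limma; 8.02 with a pseudocount of 1 and 4.85 with one of 64), NIGT1 by 2.96 (SE 0.35), SPP1 by 2.41 (SE 0.12), SPX5 by 2.33 (SE 0.28), OsPht1;4 by 2.00 (SE 0.18) and OsPHO1;2 by 0.96 (SE 0.20). SPX1 (-1.06), SPX2 (-0.95) and SPX3 (1.22) were not called, and the SPX and PHO1 list gave 3 rises of 7 (adjusted p = 0.25), or 3 of 5 with SPX1 and SPX2 left out (median log2 0.96, adjusted p = 0.0222; adjusted p = 0.269 with an estimated correlation). OsPht1;8 fell, at -1.07 (SE 0.25), in a transporter list with 1 rise and 2 falls of 7 (adjusted p = 0.701). Membrane lipid genes gave 1 rise and 1 fall of 5 (adjusted p = 0.312), with MGD3, named after its value was seen, at 0.26 (adjusted p = 0.309). SPX4 rose by 0.54, a call lost without double mutant +P array 2 (0.50) or 3 (0.52) or double mutant -P array 2 (0.50) or 3 (0.47), and OsPHO1;3 gave 0.15. PHR3 fell, at -0.78, a call lost without double mutant +P array 1 (-0.63) or 3 (-0.77) or double mutant -P array 3 (-0.62), while PHR1 (-0.12) and PHR2 (0.12) were not called. TUB6 rose by 2.66, SS1 by 2.33, GH3.2 by 2.37, HS1 by 2.89 and TIP1 by 2.98. Nramp1 fell from 1096 to 72.4 units (log2 -3.57, SE 0.38). OsPht1;1 was again called in opposite directions on 2 probe sets (log2 -1.02 and 1.96).

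Pathogenesis-related, diterpenoid, jasmonate and WRKY genes fell as lists. These falls are measured from the same 3 double mutant +P arrays as the rises for genotype at +P, so they are not separate evidence. Pathogenesis-related genes gave 8 falls and no rise of 10 (median log2 -1.52, adjusted p = 7.67e-07; adjusted p = 0.0239 with an estimated correlation), with Cht2 at -3.89 (SE 0.33), CH16 at -3.66 (SE 0.20) and Cht4 at -3.19 (SE 0.46). Diterpenoid genes gave 10 falls and 2 rises of 14 (median log2 -1.19, adjusted p = 0.0036; adjusted p = 0.296 with an estimated correlation), with KS10 at -3.39 and CPS4 at -2.92. Jasmonate genes gave 12 falls and 2 rises of 30 (median log2 -0.58, adjusted p = 0.000747; adjusted p = 0.296 with an estimated correlation), with LOX9 at -2.95, and WRKY factors 5 falls of 6 (median log2 -1.99, adjusted p = 0.000731; adjusted p = 0.251 with an estimated correlation). ICL (log2 -4.12), STLP3 (log2 -3.53), Pir7b (log2 -3.11), ACC2 (LOC4336750, log2 -3.10) and LTR1 (log2 -2.98) were among the largest falls of genes with a name beyond a LOC number. SGR fell, at -1.46 (SE 0.16), in a senescence list with 1 fall of 5 (adjusted p = 0.206). Of the 8 ratios of 3-prime to 5-prime control signal, one of 2 for Gapdh and that of ubiquitin were higher (log2 differences 0.40 and 0.49) and that of ef1a lower (-1.29) by more than 1 SD at -P than at +P.

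Photosystem genes rose, 6 of 7 (median log2 0.59, adjusted p = 7.84e-05; adjusted p = 0.251 with an estimated correlation), with RCABP69 up by 0.79 and PSAH by 0.75. Carbon fixation genes gave 4 rises of 5 (median log2 0.48, adjusted p = 0.0151; adjusted p = 0.296 with an estimated correlation), with FBPase up by 0.60; under quantile normalization that shift was lost (median 0.07), with RBCS at -0.05 and RCAA1 at 0. Ribosomal protein genes gave 9 falls of 23 (median log2 -0.29, adjusted p = 0.000113; adjusted p = 0.296 with an estimated correlation), with 60SP0 at -0.79. Auxin response genes gave 8 rises of 30 (median log2 0.47, adjusted p = 0.00436; adjusted p = 0.251 with an estimated correlation), with IAA2 up by 1.51. The changes of these lists too are measured from the double mutant +P arrays used for genotype at +P. Where they reverse the direction found there, they are not separate evidence. The other 12 tested lists had adjusted p from 0.0582 to 0.808; glutathione S-transferases (median 0.10) and iron genes (median 0.15) had medians above 0 and tests pointing downward. In total 7473 probe sets changed, 4192 upward and 3281 downward, and 2778 by at least 2-fold, 1180 upward and 1598 downward.

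**Figure D3:**
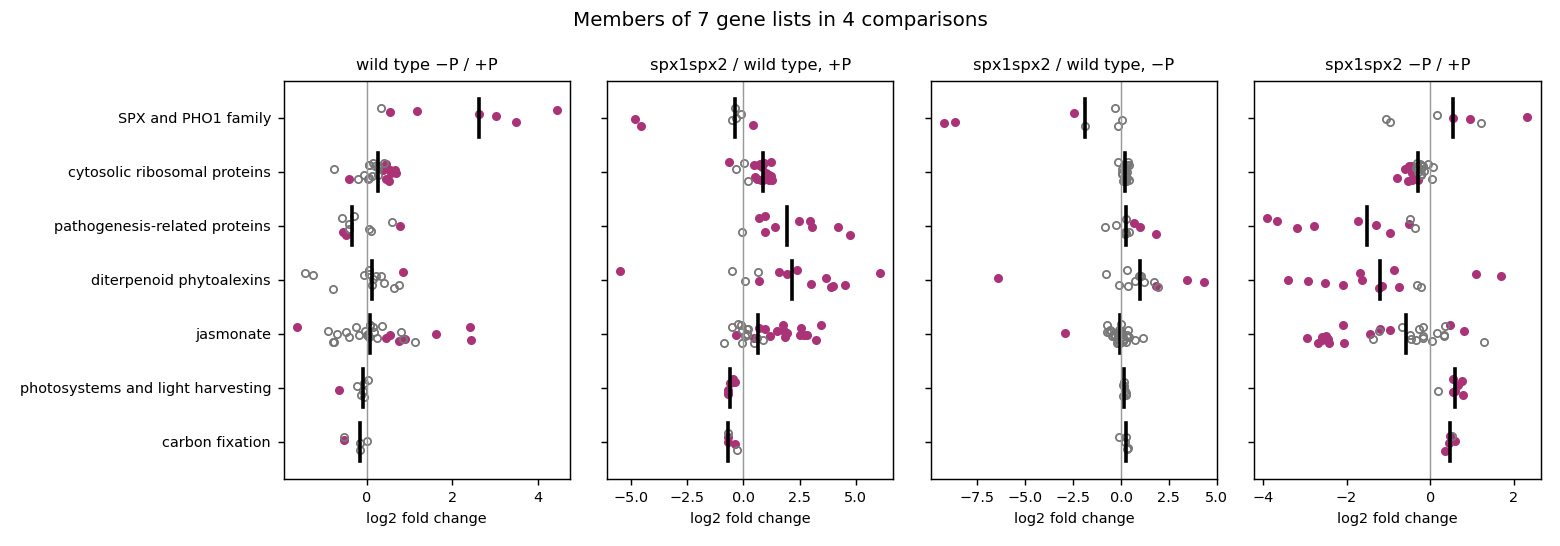
Log2 fold changes of the member genes of 7 lists (horizontal axis, scales differ between panels) in the first 4 comparisons; filled points passed the test, open points did not, and black lines are medians. Pathogenesis-related genes have medians of 1.94 for double mutant against wild type at +P and -1.52 for double mutant -P against +P.

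The interaction compares the response to phosphate withdrawal in the double mutant with that in the wild type. SPX5 responded less in the double mutant, by log2 -2.11 (SE 0.39, n = 3 per group, adjusted p = 0.00255 with limma). It was -2.07 with a pseudocount of 1 and -2.06 with one of 64. The name of its probe set marks a match to several transcripts, so a part of SPX1 or SPX2 signal was not excluded. Named after their values were seen, OsPht1;8 gave -1.86 (SE 0.35, adjusted p = 0.00267), MGD3 -1.07 (SE 0.23, adjusted p = 0.00694) and SPP1 -0.62 (SE 0.18, adjusted p = 0.0299). The SPP1 call was lost without wild-type +P array 1 (-0.61) or 2 (-0.59), wild-type -P array 2 (-0.61) or 3 (-0.55), double mutant +P array 1 (-0.60) or 2 (-0.59) or double mutant -P array 1 (-0.55) or 2 (-0.56), and also under median centring (-0.53, adjusted p = 0.0669) and without the mean-variance trend (adjusted p = 0.101). Phosphate transporters and membrane lipid genes as lists had an adjusted p of 0.572 each. The value of MGD2 is not settled, as its +P signals lie near background: it was -0.13 (SE 0.51, adjusted p = 0.923), 1.24 with a pseudocount of 1 and -0.85 with one of 64. Pathogenesis-related genes gave 6 negative interactions of 10 (median -1.16, adjusted p = 3.08e-05; adjusted p = 0.0705 with an estimated correlation), with Cht2 at -4.49 (SE 0.47). Diterpenoid genes gave 5 negative and 1 positive of 14 (median -1.18, adjusted p = 0.00681; adjusted p = 0.252 with an estimated correlation), with KS10 at -3.79 (SE 0.67). None of 3 class III peroxidases was called. ICL (-4.23, SE 0.93) and LEA19 (-3.84, SE 0.46) were also negative. BURP2 (2.70, SE 0.49), 0sFRO1 (2.07, SE 0.22), TUB6 (1.77, SE 0.25) and MFT1 (1.66, SE 0.20) responded in the positive direction. PHR3 gave -1.71 (SE 0.31). Photosystem genes gave 7 positive interactions of 7 (median 0.77, adjusted p = 6.14e-07; adjusted p = 0.153 with an estimated correlation) and jasmonate genes 11 negative of 30 (median -0.76, adjusted p = 5.69e-05; adjusted p = 0.189 with an estimated correlation), with JAZ11 at -4.19 (SE 0.67). Of 4110 probe sets with an interaction, 2103 were positive and 2007 negative, and 1905 exceeded 2-fold, 638 positive and 1267 negative. Median centring gave 2729 positive and 1617 negative, and omitting the mean-variance trend gave 2712 calls. Of the 4110, 3687 were also called between genotypes at +P, and 3509 of these were not called between genotypes at -P. The interaction uses the +P arrays of both genotypes with the opposite sign to the genotype effect at +P. Part of this overlap is therefore built in.

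A further comparison set the starvation response of the wild type beside the effect of genotype at +P. Both use the same 3 wild-type +P arrays, too few to give each comparison 2 of its own, so the shared controls are part of any likeness. Across probe sets, which are not independent replicates, the log2 changes correlated with r = 0.236, below the mean of 0.500 (0.484 to 0.520) in 100 simulations with shared controls and no effect. Their covariance was 0.109, against a simulated mean of 0.0837 (0.0799 to 0.0878). The difference of 0.0252 estimates the covariance of the effects only if all groups have the same spread, as the simulations took them to have. With 1 of those arrays for one comparison and 2 for the other, a test added after the results were seen, the covariance was 0.0186 on average over the 6 ways (0.00462 to 0.0307). Higher in both were 733 probe sets, against 249.8 from n1*n2/N, which leaves out the shared controls, and at most 1 in the simulations, which leave out the effects, so that neither gives the number for effects that are not shared. Lower in both were 843, against 242.3; higher in the starved wild type and lower in the double mutant were 279, against 272.9; the opposite held for 243, against 221.8. Thus 33.1% of the probe sets that rose in the starved wild type and 42.9% of those that fell were called the same way in the double mutant at +P. LEA19 and GSTF1 (1.30 in the double mutant) were higher in both, and NIA1 (-0.76 in the double mutant) and PSB28 were lower in both. The counts in both depended on array scaling: median centring gave 425 higher and 1442 lower, and without the trend they were 432 and 416. Without wild-type +P array 1 they were 421 and 479 and without wild-type -P array 2 they were 412 and 505; the lower count was also 553 without wild-type +P array 2 and 561 without wild-type -P array 3. Of the probe sets called in the starved wild type, 67.9% had the same sign in the starved double mutant and 35.9% were called the same way.

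Genotype differences present in both conditions were examined by gene order. Of 15624 placed genes, 53 differed by at least 4-fold in the same direction at +P and -P, 19 higher and 34 lower in the double mutant, SPX1 and SPX2 included. They lay on chromosome 6 (16 genes), chromosome 11 (12 genes), chromosome 2 (9 genes) and 8 other chromosomes. Among the 100 genes nearest SPX1 on chromosome 6, 50 on each side, 9 were among them (9% against 0.339% of all placed genes), and among the 100 nearest SPX2 on chromosome 2 there were 0. All 9 were lower in the double mutant, LOC4341377, 46 genes from SPX1, by the most (log2 -9.26 at +P and -9.05 at -P), and CYP76M7 was the nearest at 12 genes. Another probe set of LOC4341377, near background, gave -2.16 at +P and -2.01 at -P, the latter not called.

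**Figure D4:**
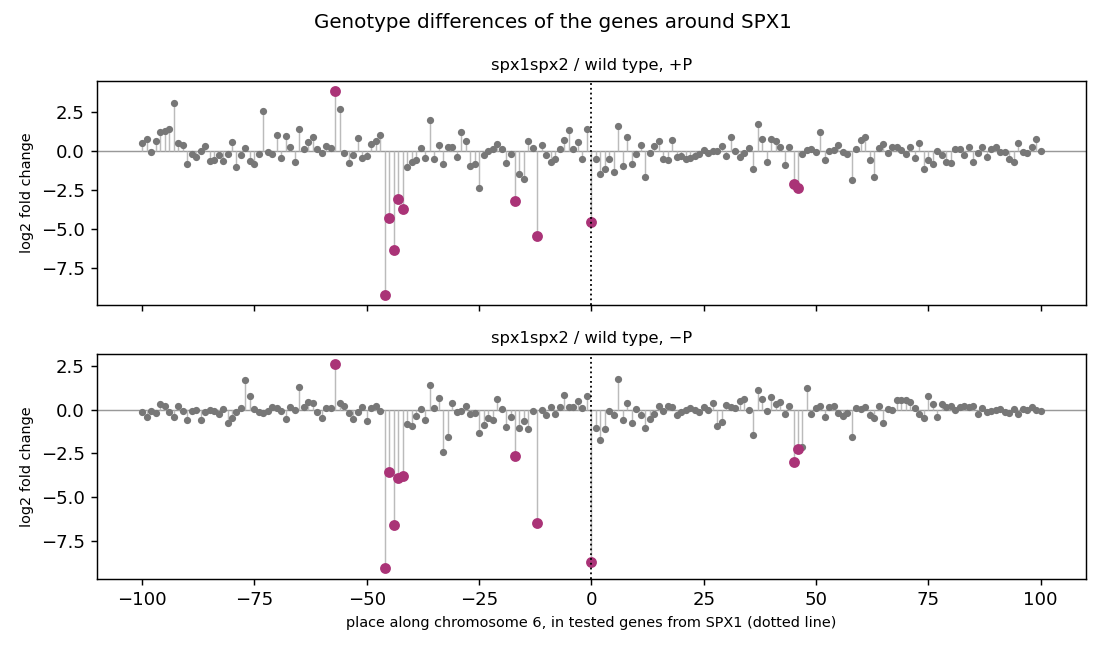
Log2 fold change of double mutant against wild type for tested genes within 100 genes of SPX1 (horizontal axis, gene order on chromosome 6), at +P (top) and at -P (bottom); each point is a gene. Purple points differ at least 4-fold the same way in both conditions, such as CYP76M7 at -5.48 and -6.44.

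The authors' deposited table for the wild type lists 6186 probe sets at a p under 0.05, that for genotype at +P lists 10247 and that for genotype at -P lists 1676. Of the calls made here, 99.6%, 99.3% and 99.4% had the same sign in the authors' deposited tables, and 3196, 6444 and 629 were called in both. In the authors' deposited table MGD2 changed by log2 7.29 in the starved wild type, and by -0.18 with p = 0.379 for genotype at +P.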

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

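The interaction results were marked because the response to phosphate withdrawal differed between the genotypes; the defence tests, the unique probe sets, the count of neighbours of SPX1, the SPX list without SPX1 and SPX2 and the separate wild-type +P arrays were chosen after the results were seen. The difference held for 4110 probe sets. Among 100 splits of the 12 arrays into 4 groups the real one alone reached that number (1 of 100, highest other 2202). The other splits mix arrays of different genotype and phosphate level. This puts those effects into the spread or the interaction, so the splits cannot test the interaction by itself. Values were ranked only among called genes with a name beyond a LOC number. The largest positive values were 2.70 (BURP2), 2.56 (CDKB2-1), 2.07 (0sFRO1), 1.92 (MTP4), 1.77 (TUB6), 1.66 (MFT1), 1.60 (OsC3H54), 1.55 (BGLU3), 1.499 (OsC3H2) and 1.49 (OsSig2B) log2 units. The largest negative values were -4.49 (Cht2), -4.43 (SPX2), -4.23 (ICL), -4.19 (JAZ11), -4.09 (SPX1), -3.84 (LEA19), -3.79 (KS10), -3.65 (STLP3), -3.53 (JAZ9) and -3.29 (Cht4), and of the phosphate genes SPX5 gave -2.11 and PHR3 -1.71. SPX1 and SPX2 are the mutated genes and stayed at 83.3 units or lower in the double mutant, so their values mainly restate the rise in the wild type. The CDKB2-1 call was lost without any 1 of the arrays but wild-type -P array 3 and double mutant +P array 2 (1.99 to 2.68), and the MTP4 call without wild-type +P array 1 (1.56), wild-type -P array 1 (1.68), double mutant +P array 3 (1.86) or double mutant -P array 2 (1.72) or 3 (1.82). The CDKB2-1 call was also lost with a pseudocount of 1 (3.68, adjusted p = 0.0638), quantile normalization (2.43), no filter, a replicate block or no mean-variance trend. Its lowest group mean was 34.99 units, near background, and a pseudocount of 64 gave 1.44, so its size and rank are not settled. The JAZ9 and MTP4 calls were lost without the trend and the STLP3 call with a pseudocount of 1. The sizes for MTP4, LEA19, Cht4 and STLP3 rest on signals near background too.

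For the same reason 10 lists were marked, by their median interaction: photosystems 0.77, carbon fixation 0.62, ribosomal proteins -0.64, pathogenesis-related proteins -1.16, jasmonate -0.76, SPX and PHO1 family -1.39, diterpenoid phytoalexins -1.18, WRKY factors -0.82, heat shock proteins -0.49 and glutathione S-transferases -0.86. With an estimated correlation their adjusted p lay between 0.0705 and 0.592. With SPX1 and SPX2 left out, the SPX and PHO1 family gave -0.39 (adjusted p = 0.151), so its shift rests on the mutated genes. Carbon fixation lost its call under quantile normalization (0.28). WRKY factors, heat shock proteins and glutathione S-transferases lost theirs under several settings, with medians from -0.64 to -0.83, from -0.47 to -0.83 and from -0.73 to -0.91. Among these settings WRKY factors lost it without wild-type +P array 1 (-0.72) or 3 (-0.70), wild-type -P array 1 (-0.73) or 2 (-0.70), double mutant +P array 2 (-0.64) or double mutant -P array 2 (-0.83). Heat shock proteins lost it without the same 6 arrays (-0.53, -0.63, -0.75, -0.50, -0.47, -0.65) or double mutant -P array 3 (-0.70). Glutathione S-transferases lost it without wild-type +P array 1 (-0.76) or 3 (-0.88), wild-type -P array 2 (-0.73) or 3 (-0.91), double mutant +P array 3 (-0.80) or double mutant -P array 2 (-0.81).

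In the comparisons of 2 groups of 3 arrays there are only 10 splits, too few for a share under 0.05. The real splits gave 4176, 7899, 849 and 7473 calls, in the order of the report, and the highest other splits 2, 0, 2 and 0; the real one alone (1 of 10) reached its number in each.

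Of the probe sets called in the starved wild type, a part was called the same way in the double mutant at +P. Both comparisons use the same wild-type +P arrays. Sharing the wild-type +P arrays gave a covariance up to 0.0878 in the simulations, and the value was 0.109. The simulations used the same spread for all groups. Pairs of wild-type +P arrays differed with an SD of 0.720 to 0.761 in log2. That SD was 0.660 to 0.707 for wild-type -P, 0.651 to 0.689 for double mutant +P and 0.701 to 0.768 for double mutant -P. Shared arrays may therefore give more than was simulated, and the simulations cannot tell whether they account for all of the covariance. With separate wild-type +P arrays the covariance was 0.00462 to 0.0307, above 0 in each of the 6 ways, and r was 0.00837 to 0.0539. All 6 ways use the same wild-type -P and double mutant +P arrays, so they are not independent. A loss of RNA quality in both groups would raise most 3-prime to 5-prime ratios by over 1 SD in both. Only 1 of 8 moved the same way by over 1 SD in both, a Gapdh ratio, and it was lower (log2 differences -0.24 and -0.54).

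The pathogenesis-related, diterpenoid and jasmonate lists of defence genes were higher in the double mutant at +P. With an estimated correlation only the pathogenesis-related list, of chitinase genes and PBZ1, kept its call. The tests of paralogs and scaling below used that list alone. If signal shared between paralogs made the whole shift, unique probe sets would lose it. Their pathogenesis-related median was 1.42, against 1.94 with all probe sets, so shared signal as a part of the shift was not excluded. If array scaling were the cause the median would move toward 0 by over 1, and its largest move was -0.0554. The median change of all probe sets was -0.0777, and it was -0.063 under quantile normalization and -0.133 under median centring. With so small a change of scale a move of over 1 was hardly possible, so this test cannot decide. It shows only that these scalings barely changed the list median. Poorer RNA would raise 3-prime to 5-prime ratios, and 0 of 8 were higher by over 1 SD while 2 were lower. These tests leave open a biological difference, a difference in growing conditions or infection, or better RNA in the double mutant, which could not be told apart here.

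Large genotype differences present in both conditions crowd on chromosome 6. The densest window of 50 genes held 8, against 3 at the 95th percentile of 10000 random sets, and a share of 1e-04, the smallest these draws can give. This fits linked sequence from another genetic background near SPX1, in which probes may match less well or genes may differ. Genes such as CYP76M7 and PLD2 in that region may therefore differ for reasons other than the loss of SPX1 and SPX2. Such large differences were not confined to that region. Of the 53 genes 12 lie on chromosome 11, which holds neither mutated gene, and whether they come from another background was not tested.

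Some reporter probe sets, which no comparison of the report uses, were marked for signal in probe sets that were left out of all tests. One gave 4.95 ± 0.41 units in the wild type at +P, 19.8 ± 14.4 at -P, and 23070 ± 2771 and 26306 ± 4337 in the double mutant at +P and -P. Another gave 8.47 ± 4.36, 16.3 ± 11.6, 319 ± 20.6 and 5420 ± 940.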

How the results depend on the processing

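Of 6844 values of named genes under the alternatives, 6342 kept direction and side of the threshold, 462 lost the call, 17 gained it and 23 turned. Of 1000 list shifts 882 kept both, 113 were lost and 5 gained. For dim genes, with signals close to background, the size of a log2 change depends on the pseudocount. The cause of each change below was not tested, except that the 2-fold minimum and the stricter filter keep fewer probe sets by construction.

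With a 2-fold minimum the counts were 1172, 2764, 475, 2778 and 1905, in the order of the report. Without the trend they were 2458 (wild type -P), 545 (genotype at -P) and 2712 (interaction), and the authors' deposited table gave 1676 for genotype at -P. Leaving out 1 array gave 2481 to 4216 for the wild type and 451 to 878 for genotype at -P. Lists shifted numbered 5, 4 and 6 (genotype at +P, at -P, interaction) with the 75th-percentile filter; 1, 1, 1, 1 and 0 with an estimated correlation; 10, 13 and 13 (wild type, genotype at +P, double mutant -P) with fry directional, 14, 20 and 20 with fry mixed; 5 at +P with unique probe sets; 6 for the interaction with SPX1 and SPX2 left out of the SPX list; and, leaving out 1 array, 1 to 2 (wild type) and 5 to 9 (genotype at -P). For the overlap, covariance was 0.226 with a pseudocount of 1 and, with separate wild-type +P arrays, 0.0186 with r = 0.0321; higher in both were 425 (median centring), 432 (no trend) and 412 to 833 (leaving out 1 array), and lower in both 1442, 416 and 479 to 860.

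Values that turned were, under quantile normalization, PPDKB 0.0379 (wild type), RCAA1 0.0141 (genotype at +P), CAB2R -0.00838 (genotype at -P), RCAA1 0 and RBCS -0.0478 (double mutant -P); under median centring, PHR2 0.0304 and a peroxidase 0.0144 (genotype at -P) and PHR1 0.0407 (interaction). Leaving out 1 array gave ranges across 0 for PPDKB (-0.0705 to 0.0556, wild type), OsPHO1;2 (-0.230 to 0.0351, genotype at +P), CHS (-0.179 to 0.647, double mutant -P) and, for genotype at -P, OsPht1;1 (-0.0630 to 0.233), RPS21 (-0.0360 to 0.252), OsPHO1;3 (-0.0295 to 0.0859), PHR2 (-0.0452 to 0.0150) and the peroxidase (-0.400 to 0.439).

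With a replicate block the counts were 4242, 7937, 874, 7511 and 4176. Of these, 3923, 7582, 770, 7152 and 3865 were also called without the block. Among values of named genes 4 lost the call and 1 gained it, and 1 list shift was lost. Arrays correlated best with their own number in 0, 3, 2 and 1 of 3 cases for the 4 comparisons (r from -0.0541 to 0.111), so the numbers were not taken to pair the samples.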

Other observations

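Gene families defined by shared symbols, 104 in all, were tested after the results were seen; none of those named here keeps its call with an estimated correlation (adjusted p 0.530 to 0.802). In the starved wild type the aquaporin family PIP, which by its symbol also takes in the lipid kinase gene PIP5K, shifted upward (5 of 9 rose, median log2 0.80, adjusted p = 0.0365), with OsPIP2;7 up by 1.54 (SE 0.26) and OsPIP1;3 by 1.23 (SE 0.16). Metallothioneins gave 3 rises of 6 (median 0.51, adjusted p = 0.0474), with MT1B up by 1.00 (SE 0.19). Calmodulin-like genes gave 8 falls and 1 rise of 21 (median -0.47, adjusted p = 0.0375), with CML4 at -1.08 (SE 0.17) and CML1 at -0.77 (SE 0.15). Under quantile normalization and median centring these medians were 0.82 and 0.66, 0.59 and 0.37, and -0.45 and -0.61.

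In the double mutant, calmodulin-like genes gave 9 falls and 1 rise of 21 on phosphate withdrawal (median -0.32, adjusted p = 0.0206), with CML31 at -2.67 (SE 0.33), CML5 at -2.36 (SE 0.19) and CML4 at -2.12 (SE 0.17). Heat shock factors gave 9 falls of 17 (median -0.83, adjusted p = 0.0227), with HSF23 at -2.50 (SE 0.33) and HSF10 at -1.59 (SE 0.31). Jasmonate repressors of the JAZ family gave 9 rises and 1 fall of 12 for genotype at +P (median 1.73, adjusted p = 0.00762) and 7 falls and 1 rise on phosphate withdrawal in the double mutant (median -1.51, adjusted p = 0.0154). Both JAZ results use the same double mutant +P arrays, so they are not separate evidence. Cellulose synthases were lower in the double mutant at -P as a family (median -0.77, adjusted p = 0.0037), with 1 of 9 genes called. No direction turned under either scaling.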
